A study of Arabidopsis thaliana with 6 samples.

How the data were processed

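Whole-plant RNA from 3 wild-type and 3 rli samples was measured on Affymetrix ATH1 arrays. The groups and replicate numbers were taken from the sample titles. The deposited values are linear probe set intensities, made with MAS5 and GCOS per the submitters' processing notes, with versions not given in the sources used here. In the deposited intensity values the mean without the lowest and highest 2% of probe sets was the same on all arrays, at 100.01 on each, so the values were used as deposited and moved to the log2 scale. The median intensities still differed, at 35.8, 36.6 and 53.0 on wild-type replicates 1 to 3 and 45.7, 38.2 and 46.3 on rli replicates 1 to 3. No detection calls were used here.

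Each of the 22810 probe sets was named through the probe gene table of the platform, which listed 14016 of them, 13513 with 1 gene and 503 with several. The other 8794 are unnamed here. Of the probe sets with 1 gene, 13436 were found in the reference gene table (assembly TAIR10.1), 1551 of them with a symbol. No name was taken from a probe set with several genes, and no coordinates were used beyond the order of genes. The 24 lists hold 449 loci, of which 74 had a named probe set. None of the 3 RLI loci had one, so the planned reading of the RLI transcripts gave no value.

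The 64 control probe sets were left out, and a probe set was tested if its mean log2 value over all arrays was at or above the 40th percentile, 4.63 (an intensity of 24.7), which left 13648, of which 7292 have 1 gene and represent 7248 loci. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) on genotype alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The stage label differs exactly as genotype does and could not be a covariate. Lists with at least 5 tested loci were tested with camera (preset correlation 0.01) with 1 probe set per locus, that with the highest mean, against the tested loci with 1 gene. Smaller lists were counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

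The named genes were chosen by a rule fixed before the data were examined. They are the RLI genes, the 12 largest rises and 12 largest falls among changed probe sets with separate groups and 1 gene with a symbol, and in each list the 2 members with the largest change each way or, where none passed, the 2 with the smallest p. UF3GT, COR15B, COR47, SAG29, SAG101, WRKY6, SBPASE, THI2.1, CCL, PSBW, PSBY and RCA were named after their values were seen. The scripts were tested on simulated data with 200 changed genes among 13648, which recovered 9.5% at a log2 difference of 1 with 0 false calls, 83% at 2 with 11 false among 177 calls and 94% at 3 with 12 false among 200 calls.

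The alternatives tried were quantile normalization, median centring, filters at the 20th and 60th percentiles or none, the 10th percentile of all values (2.45) added before the log, a floor at the 20th percentile (9.34), no intensity trend, robust variance, array weights, the replicate number as a block, each array left out in turn, and for lists an estimated correlation, fry, means over probe sets of a locus, and probe sets that may cross-hybridise left out. A covariate of the 3'/5' ratio was added after seeing the data, as were the plastid-encoded genes and the families of genes that share the letters of a symbol.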

Results

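Transcript levels were measured on 6 one-colour Affymetrix ATH1 arrays, each hybridised with biotin-labelled RNA from whole plants of Arabidopsis thaliana grown on soil. The arrays fall into 3 of wild type and 3 of a mutant labelled as an rli T-DNA insertion line. RLI, the RNase L inhibitor or ABCE protein, is an ATP-binding protein that takes part in recycling ribosomes, and the series title puts the question as its effect on RNA stability. The arrays measure the level of each transcript at harvest, and no decay rate was analysed here. The labels give all wild-type plants the developmental stage 3.20 and all rli plants the stage 1.14, with weeks as the unit. The labels do not settle whether these numbers are ages or codes of growth stages, and no age is read from them here. The stage label differs exactly as genotype does, so each difference below is one of genotype and labelled stage together. Both groups carry the same source name, Co-1, and the same stock code, and the labels do not settle whether the mutant is in the same accession as the wild type, so a difference of background is not separated from the insertion. Each array carried 22810 probe sets, and the number of arrays limits the precision of every value. Values are log2 MAS5 intensities, differences are rli minus wild type with the standard error of the limma fit, n = 3 arrays per group, and each adjusted p is from limma with Benjamini-Hochberg adjustment over 13648 tested probe sets.

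The targeted gene could not be read. None of the 3 RLI loci (AT3G13640, AT4G19210 and AT4G30300) had a probe set named in the gene table used here, so the genotype labels were not checked against the RLI transcript.

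Between rli and wild type, 928 probe sets changed, of which 583 rose and 345 fell in rli. Among the genes with a symbol, the largest rise was that of JAL33 (AT3G16450), a jacalin-related lectin, by 5.10 ± 0.73 (adjusted p = 0.0032). Its wild-type mean lay below the filter level, and the difference was 4.63 when low values were raised to a floor. ORA47 (AT1G74930), a transcription factor of the AP2/ERF family, rose by 3.48 ± 0.34 (adjusted p = 0.00034). The drought-induced gene DI21 (AT4G15910) rose by 3.38 ± 0.27 (adjusted p = 0.00011) and the cold-regulated gene COR15A (AT2G42540), whose product protects chloroplast membranes during freezing, by 3.16 ± 0.23 (adjusted p = 9.1e-05). Among the genes with a symbol, which make up 78 of the 928 changed probe sets, the 12 largest falls ran from P1R1 (AT5G57780), at -2.04 ± 0.31 (adjusted p = 0.0043), to CCB3 (AT5G36120), at -1.12 ± 0.26 (adjusted p = 0.034).

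The other named rises included DFR (AT5G42800), the dihydroflavonol reductase of anthocyanin synthesis, by 3.26 ± 0.24, and the osmotin-like gene OSM34 (AT4G11650) by 2.67 ± 0.29. HTB11 (AT3G46030), a histone H2B, rose by 3.26 ± 0.39 and HIS1-3 (AT2G18050), a linker histone, by 2.39 ± 0.34. ZW9 (AT1G58270) rose by 3.15 ± 0.34, the zinc finger transcription factor STZ (AT1G27730) by 2.36 ± 0.22 and BETA-VPE (AT1G62710), a vacuolar processing enzyme, by 2.34 ± 0.31. CML37 (AT5G42380), a calmodulin-like protein, rose by 3.23 ± 0.63 (adjusted p = 0.015), from a wild-type mean below the filter level, and by 2.74 with the floor. Its adjusted p was no longer below the threshold after quantile normalization or without any 1 of the rli arrays, with a highest value of 0.11 over its alternatives.

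**Figure D1:**
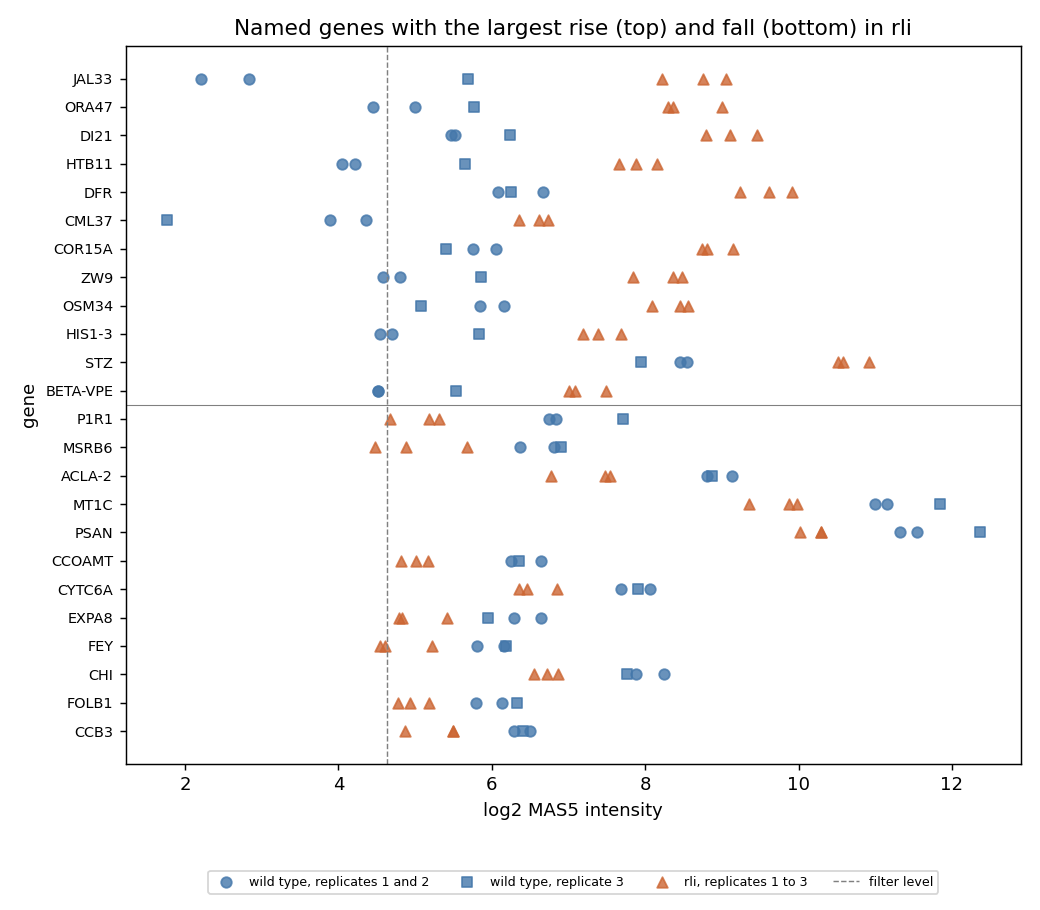
Log2 MAS5 intensity (x axis) of the 12 named genes with the largest rise and the 12 with the largest fall in rli (y axis), with 1 point per array, 3 wild-type and 3 rli arrays. The dashed line is the filter level of 4.63. In all 24 genes the points of both groups do not overlap, which the rule that chose them required.

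ACLA-2 (AT1G60810), a subunit of ATP citrate lyase, stood at -1.68 ± 0.24 and the metallothionein MT1C (AT1G07610) at -1.60 ± 0.27. The difference of PSAN (AT5G64040), a subunit of photosystem I, was -1.54 ± 0.27, that of CYTC6A (AT5G45040), a cytochrome of the thylakoid lumen, -1.33 ± 0.21, and that of MSRB6 (AT4G04840), a methionine sulfoxide reductase, -1.68 ± 0.33. CCOAMT (AT1G67980), an O-methyltransferase, stood at -1.42 ± 0.25 and EXPA8 (AT2G40610), an expansin, at -1.28 ± 0.30. CHI (AT2G43570) stood at -1.26 ± 0.21, FEY (AT4G27760) at -1.26 ± 0.31 and FOLB1 (AT3G11750), an aldolase of folate synthesis, at -1.13 ± 0.28. P1R1, ACLA-2, MT1C and CYTC6A were past the threshold in every alternative that tested them, and the other 8 falls lost the call in at least 1. EXPA8, FEY, FOLB1 and CCB3 lost it after median centring and with no filter. They also lost it without wild-type replicate 1 or 2 or rli replicate 1 or 3. FEY, FOLB1 and CCB3 lost it too without rli replicate 2 and with the filter at the 20th percentile, and EXPA8 and CCB3 after quantile normalization. The highest adjusted p-values of EXPA8, FEY, FOLB1 and CCB3 were 0.14, 0.16, 0.16 and 0.14. PSAN lost it without rli replicate 3 (adjusted p = 0.054), CCOAMT without wild-type replicate 2 (0.065) and CHI after median centring (0.085), while MSRB6 lost it without wild-type replicate 2 and without rli replicate 1 or 3 (highest 0.065).

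Of the 928 changed probe sets, 699 changed at least 2-fold, 483 up and 216 down, and 2880 had an unadjusted p below 0.05. The groups were separate in all 928, which follows largely from their selection by p-value and is no separate support. Of all tested probe sets 28.1% had separate groups, against the 10% that chance gives. The count was 332 after median centring, 593 without the intensity trend and 3181 with array weights, and it ranged from 389 without rli replicate 3 to 2085 without wild-type replicate 3. It was 497 without wild-type replicate 1, 555 without wild-type replicate 2, 403 without rli replicate 1 and 498 without rli replicate 2. Nothing in the labels says that the replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

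The gene lists fixed before the data were examined held 61 tested loci, of which 9 rose and 1 fell. In lists this short, a member that passed over all probe sets must also pass when adjusted over its list alone. For such members the second count adds no support. In the flavonoid and anthocyanin list all 3 tested members rose, DFR, AT4G14090, an anthocyanin glucosyltransferase, by 2.50 ± 0.42, and UF3GT by 2.04 ± 0.26, and the same 3 rose when adjusted over the list alone. AT4G14090, whose wild-type mean lay below the filter level, lost the call without rli replicate 2 (adjusted p = 0.058). Among 4 tested genes of abscisic acid, drought and cold, COR15A and the dehydrin gene LTI30 (2.28 ± 0.48, adjusted p = 0.022) rose, also when adjusted over the list alone. COR15B stood at 0.19 ± 0.23 and COR47 at 0.07 ± 0.28. LTI30 lost the call without the intensity trend and without wild-type replicate 1 or 2 or rli replicate 2 or 3, with a highest adjusted p of 0.10. Of 3 rapid, short-lived response transcripts, STZ and CML38 (2.00 ± 0.28, adjusted p = 0.0026) rose, 2 also when adjusted over the list alone, and CCL stood at -0.25 ± 0.18.

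The photosynthesis list was the 1 list of the 4 with at least 5 tested loci to pass the camera test, with a direction down (adjusted p = 0.0031). Its call was lost with an estimated correlation (adjusted p = 0.19), and the fry test of the list's own balance gave an adjusted p of 0.024. PSAN fell, the other 7 of its 8 tested members did not pass over all probe sets, and 3 fell when adjusted over the list alone. All 8 members had a lower mean in rli, with a median of -0.42. PSBW stood at -0.68 ± 0.21 (adjusted p = 0.091), PSBY at -0.66 ± 0.22 (0.12) and RCA, the activase of Rubisco, at -0.39 ± 0.20 (0.30). Without wild-type replicate 3, 2 of the 7 passed, PSBY (adjusted p = 0.0072) and SBPASE (0.040), and 5 of the 7 passed with array weights. With the preset correlation, the list's adjusted p lay between 0.00015 and 0.044 over 19 alternative settings, which all share the choice that the call depends on. Of the 10 splits of the 6 arrays into 3 and 3, 3 gave a list past the threshold, the real split among them.

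The RNA decay and surveillance list had 12 tested members, of which 0 changed over all probe sets or when adjusted over the list alone, with 2 below an unadjusted p of 0.05 (camera adjusted p = 0.76). The members with the smallest p were LSM1B and UPF3. LSM1B, a subunit of the decapping activator complex, stood at -0.89 ± 0.28 (limma adjusted p = 0.10). It passed with the replicate number as a block, and with the 3'/5' ratio as a covariate (limma adjusted p = 0.020), a setting chosen after seeing the data. UPF3, a factor of nonsense-mediated decay, stood at -0.54 ± 0.22 (0.19). Of 6 tested genes of cytosolic ribosomal proteins 0 changed, with 1 below an unadjusted p of 0.05 (camera adjusted p = 0.76), among them AT3G11250 at -0.61 ± 0.22 and AT2G40010, with a wild-type mean below the filter level, at 1.04 ± 0.53. Both passed without wild-type replicate 3 (adjusted p = 0.047 and 0.021) and with array weights (0.0094 and 0.0065). The 5 tested reference genes had 0 changed and 0 below an unadjusted p of 0.05 (camera adjusted p = 0.76), with PEX4 at -0.34 ± 0.19 and AT5G15710, with a wild-type mean below the filter level, at 0.83 ± 0.53. In the RNA silencing list SE stood at 0.08 ± 0.31 and AGO7 at 0.03 ± 0.49, and the translation factor EIF4A-2 at -0.05 ± 0.23. The self-test recovered 9.5% of simulated changes of log2 1 and 83% of those of log2 2, with 200 changed genes simulated, while 229 of the 928 calls in the data were of less than 2-fold, so a member that did not pass is not shown to be unchanged.

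Of 4 tested senescence genes WRKY53, a transcription factor of leaf senescence, rose by 0.99 ± 0.22 (adjusted p = 0.026), and 2 rose when adjusted over the list alone. SAG29 stood at 3.97 ± 1.14 (adjusted p = 0.072), from a wild-type mean of 3.28, below the filter level, and passed without wild-type replicate 3 (5.17, adjusted p = 0.0019), with the floor and with array weights among others. SAG101 stood at 0.45 ± 0.25 and WRKY6 at -0.54 ± 0.35 (adjusted p = 0.43; 0.016 with array weights). Of 2 tested jasmonate genes the defensin gene PDF1.2 rose by 1.68 ± 0.39 (adjusted p = 0.034; 1 when adjusted over the list alone), and THI2.1 stood at 0.88 ± 0.49, passing with array weights (lowest adjusted p = 0.011) and without rli replicate 2. Both calls were lost after median centring and without the intensity trend. WRKY53 also lost it without wild-type replicate 1 or any 1 of the rli arrays (highest adjusted p = 0.31), and PDF1.2 without wild-type replicate 1 or 2 or rli replicate 3 (highest 0.15). GI, a gene of the clock and of flowering time and the 1 tested member of the evening clock list, stood at 1.16 ± 0.31 (adjusted p = 0.057; 1 rose when adjusted over either of its lists alone), and AGL24 of the flowering list at -0.27 ± 0.28. In the evening clock list, adjusting over 1 tested member leaves its p-value as it was. GI passed without wild-type replicate 3 (adjusted p = 0.015), with array weights (0.0020) and with the 3'/5' covariate (0.030).

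The remaining lists had 0 changed members over all probe sets. In the glucosinolate list BCAT4 stood at -0.50 ± 0.18 (adjusted p = 0.14), 1 fell when adjusted over the list alone, and UGT74B1 stood at 0.39 ± 0.32. BCAT4 passed without wild-type replicate 3 (adjusted p = 0.029) and with array weights (0.013). In the cell division list AUR1 stood at -0.31 ± 0.23 and PRL at -0.03 ± 0.22, and in the list of leaf polarity and shoot meristem PHV stood at 0.35 ± 0.28, passing with array weights (adjusted p = 0.036), and YAB3 at -0.14 ± 0.23. The heat shock gene AT5G48570 stood at -0.16 ± 0.48 and the root gene PYK10, the marker of another organ in these whole plants, at 0.21 ± 0.19. Of these members BCAT4 alone had an unadjusted p below 0.05. The lists of RLI genes, floral organ identity, salicylic acid defence, morning clock, phosphate starvation and seed maturation had 0 tested members and were not analysed here.

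**Figure D2:**
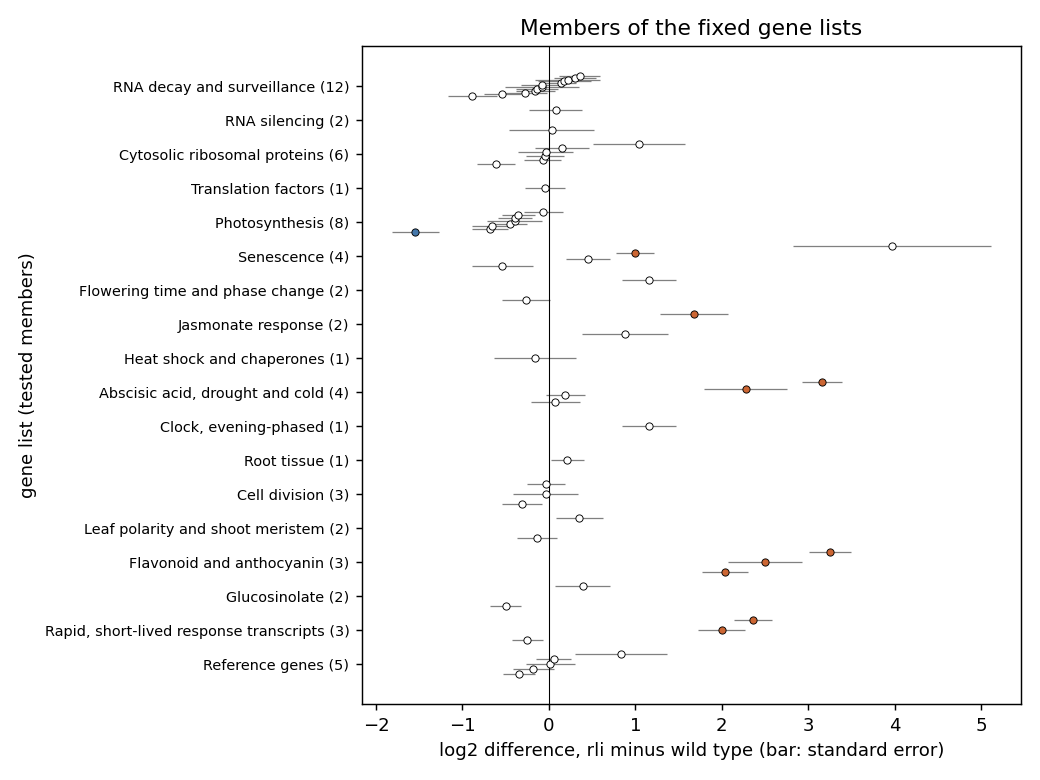
Log2 difference, rli minus wild type (x axis), of each tested member of the 18 gene lists with a tested locus (y axis), with the standard error as a bar and n = 3 arrays per group. Filled points are past the adjusted threshold, orange for a rise and blue for a fall, and all 3 flavonoid and anthocyanin genes are filled in orange.

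The control probe sets compared the 3' with the 5' end of the control transcripts, a reading of RNA integrity and labelling. The mean log2 ratio over 6 control pairs was 2.45 ± 0.36 (SD, n = 3) in wild type and 2.58 ± 0.16 (SD, n = 3) in rli, a difference of 0.13 that was within the spread (exact two-sided permutation p = 0.7, where 0.1 is the smallest that 3 against 3 allows). Without wild-type replicate 3 the difference was 0.32, and without wild-type replicate 1 it was -0.04. Wild-type replicate 3 stood apart, with correlations across all probe sets of 0.76 with each of the other wild-type arrays and of 0.77, 0.75 and 0.79 with rli replicates 1, 2 and 3. It had the highest mean ratio, 2.83. The 25S ribosomal RNA probe set read 1927 on that array, 285.2 and 344.3 on the other wild-type arrays and 863.1 to 1319 on the rli arrays.

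**Figure D3:**
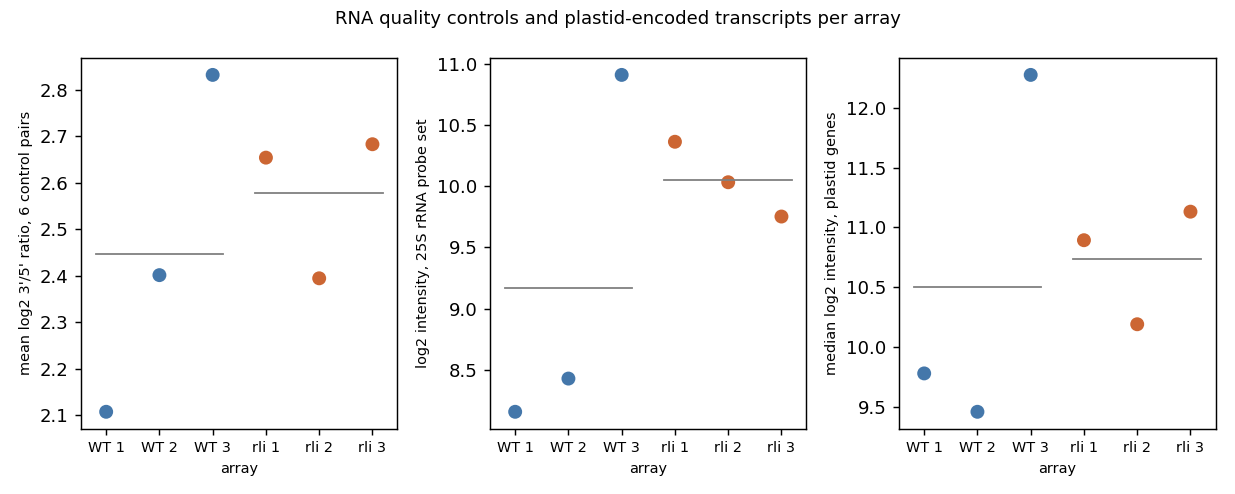
Mean log2 ratio of 3' to 5' control probe sets, log2 intensity of the 25S rRNA probe set and median log2 intensity of the plastid-encoded probe sets (y axes) on each of the 6 arrays (x axis), with the group mean as a line. Wild-type replicate 3 is highest in each panel, with a plastid median of 12.28.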

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

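The 3'/5' covariate and the plastid values were chosen after seeing the data. Against 928 changed, 583 up and 345 down, with 699 at least 2-fold, median centring gave 332, 227 and 105, with 328. Without the intensity trend 593 changed and 182 fell. Array weights gave 3181, 1719 and 1462, with 1271, and the 3'/5' covariate 2134, 1307 and 827, with 1103. Leaving out each array in turn gave 389 (without rli replicate 3) to 2085 (without wild-type replicate 3) changed, 282 to 1190 up, 102 to 895 down and 389 to 1108 at least 2-fold. The cause was not tested, but fewer arrays lower the degrees of freedom, while leaving out wild-type replicate 3 raised the count. The calls without wild-type replicate 3 included 927 of the 928. Of the calls, 0 changed sign in any of the 18 alternatives, with all 928 tested in each except the filter at the 60th percentile, which tested 784. The groups were separate in all 928, so only quantile normalization, median centring and the 3'/5' covariate could have changed a sign. The unchanged signs are therefore little support. Of the 12 named rises 11 and of the 12 named falls 4 were past the threshold in every alternative that tested them. Of 51 tested list loci that did not pass, 14 passed in at least 1 alternative, 7 of them without wild-type replicate 3. Lists past the threshold numbered 1, but 2 with no filter, where the abscisic acid, drought and cold list had 5 tested loci and passed (adjusted p = 0.0011), and 0 with an estimated correlation. The 3'/5' difference of 0.13 ranged from -0.040 to 0.32 with each array left out. The plastid median of 0.15 ranged from -0.22 to 0.81 with each array left out and was 0.35 after quantile normalization and 0.76 with array weights. The replicate number as a block gave 1300 changed probe sets, LSM1B and SAG29 among those gained. Deviations of samples with the same number correlated at -0.09, 0.33 and 0.32. Wild-type replicates 2 and 3 correlated best with the rli sample of their own number, and wild-type replicate 1 with rli replicate 2 (0.27). Deviations from a mean of 3 arrays depend on each other, so these values cannot show whether the samples were paired. The RLI transcripts gave no value under any alternative, and without detection calls a group mean below the filter level is read as a dim signal only.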

Other observations

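The loci without a symbol and the gene families below were chosen after their values were seen, and so were the tests of RNA degradation, of a mixed sample and of single arrays held out, of rRNA against plastid transcripts and of neighbouring genes counted once. AT3G22240 rose 97.3-fold (standard error 0.26 on the log2 scale, limma adjusted p = 4.0e-06) and AT1G50290 fell by 4.18 ± 0.19 (5.1e-06), both past the threshold in every alternative that tested them. AT3G47250 stood 7.05 ± 1.27 higher from a wild-type mean below the filter level, or 5.39 higher with low values raised to the floor, and lost its call with robust variance and without rli replicate 1 or 2 (highest adjusted p = 0.12). Of other single loci, AT4G15680 stood at -3.36 ± 0.27 and AT3G62950 at -2.97 ± 0.34, both to an rli mean below the filter level. Among the 474 changed probe sets without a single named gene, 304 rose and 170 fell, with -5.18 ± 0.32 as the largest fall. The largest rise was 5.38 ± 0.45, from a wild-type mean of 2.07, below the filter level, so its size is uncertain.

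Of 29 families tested with camera, the PUB family of ubiquitin ligases was higher (2 of 7 rose, adjusted p = 0.032; 0.71 with an estimated correlation), with PUB19 at 2.13 ± 0.31, from a wild-type mean below the filter level, and PUB23 at 1.72 ± 0.27. The NRPB subunits of RNA polymerase were lower as a set (adjusted p = 0.042; 0.71 with an estimated correlation), though 0 of 6 passed singly and 4 had an unadjusted p below 0.05. All 7 PUB genes had a higher and all 6 NRPB genes a lower mean in rli, also after quantile normalization and median centring, which rescale the same arrays. Other families were as one-sided without passing camera. All 6 LSM genes were lower in rli, 3 with an unadjusted p below 0.05 (camera adjusted p = 0.11), and so were all 5 EXPA genes (0.13). The CML calmodulin-like family did not pass (adjusted p = 0.13), with CML38, CML37 and CML23 (1.54 ± 0.25) up and CML42 at -0.68 ± 0.26 and CML30 at -0.64 ± 0.26, 2 of 6 with an unadjusted p below 0.05 downward. CML37 lost its call after quantile normalization and without any 1 of the rli arrays (highest adjusted p = 0.11).

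The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 928 changed probe sets and the highest other 0, so 1 split gave as many. For lists the real split gave 1 and the highest other 1, and 3 splits gave as many.

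Wild-type replicate 3 stands apart, and over all probe sets it correlated best with rli replicate 3 (0.79) and rli replicate 1 (0.77), above wild-type replicates 1 and 2 (0.76 each). A sample wholly of rli is argued against, since the array lay nearer the other wild-type arrays at 63.2% of the 2085 probe sets called without it (exact 95% bounds 61.1 to 65.2, which take probe sets as independent), while each rli array held out likewise lay nearer the rli arrays at 88.4% to 97.9%. Its share was also below those of the other wild-type arrays (91.7% of 555 and 95.2% of 497 probe sets). Those lists and the rli lists (389 to 498 probe sets) were shorter and were called with wild-type replicate 3 in the wild-type group. The shares are therefore not like measures, and the argument against a sample wholly of rli rests on the share of 63.2% from 1 array alone. Wild-type replicate 3 lay 0.44 of the way from the wild-type to the rli mean. A mixture of both genotypes may account for part of its standing apart and cannot be told apart from noise. RNA degradation or poor labelling also stays open, as its 3'/5' ratio was the highest in 4 of the 6 control pairs, those of GAPDH and ubiquitin, and the lowest of all arrays in 1 pair of actin. Its hybridization control probe sets also read highest, at a mean log2 of 10.32. The other wild-type arrays read 8.96 and 9.37, and the rli arrays 9.38 to 9.80. What raised these controls was not tested. A difference between the plants was not tested.

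Plastid-encoded transcripts are higher in rli than in wild-type replicates 1 and 2, with 65 of 69 above both. Over all arrays 0 of 69 changed (limma, 1 with an unadjusted p below 0.05), and without wild-type replicate 3, the highest array for 66 of them, 40 rose and 0 fell. RNA quality, or priming of RNA that lacks poly(A) tails, may account for this: the plastid median and the 25S rRNA signal had a Pearson r of 0.86 over 6 arrays (exact permutation p = 0.026) and a Spearman rho of 0.77 (exact permutation p = 0.10), the 1 relation computed. Without wild-type replicates 1 and 2, r was 0.72, with wild-type replicate 3, the highest array in both measures, kept. With 3 arrays a group is too small to test alone. Within rli the 25S signal was highest on replicate 1 (1319) and the plastid median on replicate 3 (11.13). The 5S rRNA probe set ranked all 6 arrays as the plastid median did, from 38.2 on wild-type replicate 2 to 2513 on wild-type replicate 3. The 5S order is a further relation that was looked at, and no correlation or p-value was computed for it. RNA quality and genotype cannot be told apart here, because both rRNA signals were also higher on every rli array than on wild-type replicates 1 and 2. The rank correlation with the 25S signal missed its threshold, while the 5S order matched. Within the wild-type label alone the plastid median ran from 9.46 to 12.28, the latter on wild-type replicate 3. With the 3'/5' covariate the median plastid difference was -0.20.

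The 87 loci that changed at least 4-fold, of 7179 in gene order, were not spread evenly. The fullest window of 50 loci, on chromosome 4 from AT4G15680 to AT4G16710, held 6 of them, with a median of 4 for the fullest window in 10000 random orders (permutation p = 0.019), and a segment that differs between the genotypes, such as one linked to the insertion or of another accession, may account for it. Directions in the window were mixed, with DI21 up by 3.38 and AT4G16000 at -2.23. Neighbouring genes that share regulation or hybridization are also open: 5 neighbouring pairs both changed against a median of 1 in random orders (permutation p = 0.0050), and with such neighbours counted once the fullest window held 5 (permutation p = 0.13). The enrichment therefore rests in part on neighbours, and the 2 explanations cannot be told apart with these values.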
